A study of Mus musculus with 12 samples.

How the data were processed

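Inguinal white adipose tissue was taken from 12 male BALB/c mice, 6 per group, and profiled on 1-colour Agilent arrays that carry lncRNA and mRNA probes. Per the labels, the mice were aged 6 weeks, the cachexia group had been inoculated under the skin with colon-26 adenocarcinoma cells, the control group with saline vehicle, and tissue was harvested on day 21. Per the labels' protocols, total RNA was depleted of ribosomal RNA, amplified by random priming along whole transcripts and labelled with Cy3. Groups and replicate numbers came from the sample titles. The cachexia samples also carry a description that calls them littermate controls, and their titles, source names and inoculated cells were followed.

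Per the file headers, the scanner output was read with Agilent Feature Extraction 11.0.1.1, the same version as in the submitters' processing notes. The deposited spot intensities used were the processed signal, which Feature Extraction had corrected for background within each array, and the median spot and background signals. No normalization between arrays had been applied to these intensities. The deposited series table holds log2 values whose scaling method is not given in the sources used here. Each of its columns followed its own array more closely than any other (rank correlations 0.929 to 1.00). Its column medians were 3.92 to 3.93 for 10 arrays and 2.78 for cachexia 3 and 5. In cachexia 3 and 5 the median was the column's lowest value, held by 31355 and 31361 of 60819 probes. In cachexia 6, 30163 probes held the lowest value. The series values were used as an alternative.

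The log2 processed signal was reduced by each array's 75th percentile, after outlier-flagged and control spots were left out and the spots of a probe averaged. A probe was tested when well above background on at least 6 of the 12 arrays, which kept 32592 of 60915 probes, and 16148 were well above background on all 12. No spot outside the control spots was saturated. Saturation was not counted on the control spots, which include those for GAPDH, PGK1 and E1A. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. All differences are cachexia minus control. For probes with lincRNA in the name (1836, of which 330 were tested), the shift of the class was tested with camera at a preset correlation of 0.01 and with an estimated correlation. This class test was added after the data were seen.

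Arrays were compared in pairs before any group was tested. Over 8068 bright probes, the spread between 2 arrays, after a brightness trend was removed, was divided by the spread between repeated spots of 1 probe. The ratio was 1.32 to 1.53 for the 3 pairs among cachexia 3, 5 and 6, and 3.57 to 33.2 for the other pairs. These 3 arrays, at ratios below 2, were averaged to 1 replicate, so 6 control and 4 cachexia replicates entered the main comparison. The limit of 2 and the removal of the trend were settled after these ratios had been seen. An earlier version with a lower limit and no trend removal had joined only cachexia 5 and 6. The differences among the 3 arrays exceeded the spot noise alone, which leaves out the noise of separate hybridisations. The plan fixed before the data were examined counted each of the 12 arrays as a replicate. That fit is given beside the main count because the choice changes it.

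The files do not pair the probe IDs with genes, and 0 of the probe IDs matched the gene table used here. The gene lists, cell type markers, mRNA count and named genes fixed before the data were examined were therefore not analysed, nor were their alternatives. Of the rule for named genes, the conditions that need no gene name were applied to the 12-array fit: past the threshold, no overlap between groups, and well above background on all 12 arrays. The 2 largest rises and the 2 largest falls among the 5 such probes are named. This use of the rule was settled after both fits had been seen, since the averaged fit called no probe.

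The alternatives chosen before the data were examined were quantile normalization, the authors' log2 values, another reference for the percentile, 3 filters on dim probes, trend and robust variance, a stricter threshold, slide, scan day and replicate number as blocks, and each array left out. The planned normexp correction, with an offset of 50, used the median signal, since the mean signal is not a column of the files used here. The originally planned fit with 12 separate arrays was run as an alternative to the averaged one. Added after seeing the data were slide as a random block, subsets by scan day or slide, removal of arrays with a wide GAPDH difference, and that difference as a covariate. Differences of control genes were compared with exact permutation tests in Python (NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1). The limma step was tested on simulated data with 32592 probes, 200 of them changed, at the real spread and 4 against 6 replicates. It recovered 0 of 66 probes changed by 1 on the log2 scale, 9 of 67 changed by 2 and 33 of 67 changed by 3, with 2 false calls among 44. The number of arrays limits the precision.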

Results

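Adipose tissue of mice bearing colon-26 tumours, a transplantable carcinoma used as a model of cancer cachexia, was compared with that of non-bearing littermates to find lncRNAs and mRNAs involved in fat wasting. The series held 6 control and 6 cachexia arrays. Between 48.2% and 57.7% of probes were well above background on the control arrays. The shares on cachexia 1, 2 and 4 were 56.4%, 73.3% and 59.8%, and those on cachexia 3, 5 and 6 were 33.6%, 34.7% and 35.3%. Cachexia 3, 5 and 6 differed among themselves by 1.32 to 1.53 times the noise between repeated spots, against at least 3.57 times for any other pair, and were counted as 1 sample. That choice was made after the arrays had been compared with each other and before the groups were. The spread before division by the noise set them less apart. It was 0.096 to 0.141 (log2) among these 3 arrays, 0.168 between cachexia 1 and 2, and at least 0.225 between controls. Plain correlations did not set them apart. They were 0.982 to 0.985 among the 3 arrays, 0.983 between cachexia 1 and 2, and up to 0.985 between controls. The control samples and cachexia 1 were scanned on 1 day, cachexia 3, 5 and 6 on another, and cachexia 2 and 4 on a further day.

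Probe ASMM10P015130 measured -0.56 ± 1.28 (SD, n = 6) in control and 3.09 ± 0.49 (n = 4) in cachexia tissue, on the log2 scale relative to the array's 75th percentile. The difference was 3.65 ± 0.63 (SE). For ASMM10P034686 the means were -0.68 ± 0.42 and 1.47 ± 0.41, a difference of 2.16 ± 0.33. Probe ASMM10P023056 measured 2.20 ± 0.87 in control and -0.37 ± 0.39 in cachexia tissue, a difference of -2.57 ± 0.47. Probe ASMM10P022623 measured 3.79 ± 0.21 and 1.67 ± 0.27, a difference of -2.13 ± 0.27. The 4 were chosen as the largest rises and falls among probes that passed the fit with 12 separate arrays and met 2 further conditions. These were a signal well above background on all 12 arrays and 6 cachexia arrays on 1 side of the 6 control arrays. The files do not pair these IDs with genes.

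With cachexia 3, 5 and 6 counted once, these differences did not pass limma's test after adjustment over 32592 probes. The adjusted p-values were 0.353 for ASMM10P015130, 0.249 for ASMM10P034686, 0.389 for ASMM10P023056 and 0.136 for ASMM10P022623. The fit planned before the data were examined took each of the 12 arrays as a replicate, and the 4 probes were chosen for passing it. Their adjusted p-values from limma's test in that fit were 0.034, 0.0238, 0.0499 and 0.00752 in the same order, and are no separate evidence. That fit takes 3 nearly identical arrays for 3 animals. On the day that scanned both groups, cachexia 1 differed from the 6 controls by 3.58 for ASMM10P015130, 2.49 for ASMM10P034686, -2.58 for ASMM10P023056 and -2.05 for ASMM10P022623. On the slide that held both groups, the differences of cachexia 1 from 4 controls were 2.99, 2.24, -2.17 and -1.97. The direction of these differences, within the day or the slide, was fixed by the choice of probes whose groups do not overlap. Their size, and that of the group differences, was favoured by choosing the largest rises and falls from these same arrays, so it may be overstated.

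**Figure D1:**
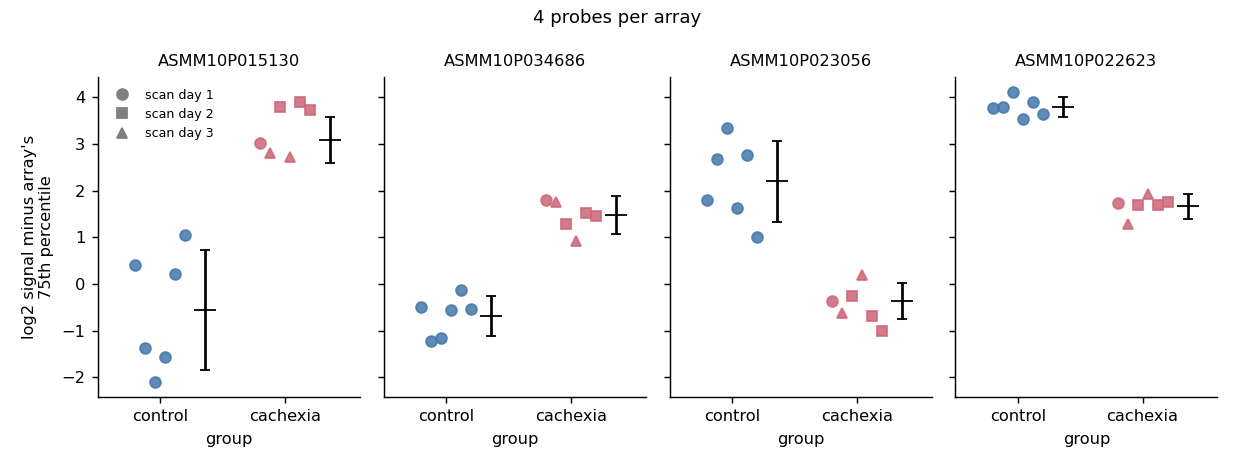
Log2 signal minus the array's 75th percentile for 4 probes, 1 point per array, with the group mean and SD over 6 control and 4 cachexia replicates as bars and the scan day as the marker shape. The 4 probes were chosen for groups that do not overlap. The cachexia means are 3.09 and 1.47 against -0.56 and -0.68 for the probes on the left, and -0.37 and 1.67 against 2.20 and 3.79 for those on the right.

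Over all probes, limma called 0 of 32592 changed between cachexia and control tissue, at 6 against 4 replicates. At an unadjusted p under 0.05, 4172 probes passed, and the smallest adjusted p was 0.109. With the 12 arrays as separate replicates, 10 probes were called, 4 higher and 6 lower in cachexia, all of them changed at least 2-fold, and 12751 passed unadjusted. All 10 had groups that do not overlap, which fixes their direction when the 3 arrays are averaged. In limma's test on the averaged data their unadjusted p was under 0.05 and their adjusted p from 0.109 to 0.389. Only cachexia 1 shared a scan day or a slide with controls, so fits with either as a block, or within the shared day or slide, compare this 1 cachexia sample with 6 or 4 controls. They called 0 probes, which says nothing about the other cachexia samples. Leaving out any 1 array or the averaged replicate left the count at 0, while the number of probes at an unadjusted p under 0.05 fell to 2427 without control 2, 2460 without control 3, 2171 without cachexia 4 and 2401 without the averaged cachexia 3, 5 and 6, and was 9805 without cachexia 1. Leaving out the 4 cachexia arrays whose GAPDH probes differed more than on any control array, a step added after seeing the data, left cachexia 1 and 2 against 6 controls and gave 30 calls, 28 higher and 2 lower. Of these 30, the direction was the same in 13 in the averaged cachexia 3, 5 and 6 and in 11 in cachexia 4, and 2 were among the 10 calls with 12 separate arrays. The 30 calls rest on 2 cachexia samples that lay closer together than any 2 controls. The spread between them was 0.168, against 0.225 to 0.696 for pairs of controls.

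A class of probes carries lincRNA, the usual short form of long intergenic noncoding RNA, in its name. Of the 330 tested, 0 were called with either count of replicates, 0 adjusted over this class alone, and 51 had an unadjusted p under 0.05. As a class they lay higher in cachexia tissue, with a median log2 difference of 0.79 and 293 of 330 probes above 0, against a median of -0.01 for the other probes. Of the 330, 183 carry human and 119 mouse in the name, with medians of 0.84 and 0.72. The shift was not particular to the class, since 246 tested probes with the ASMM10UP prefix, which the files do not define, had a median of 0.60, with 170 above 0. It was 0.23 for the lincRNA-named probes with normexp on the median signal at an offset of 50. Over the 106 lincRNA-named probes well above background on all 12 arrays it was 0.88, against a median of 0.10 for all such probes. Without the filter on dim probes the list grows to 1836 probes, with a median of 0.36 against 0.20 for all probes. The shift passed camera's test at a preset correlation (p = 4.84e-12) but not with an estimated one (p = 0.166 with an estimated correlation). It was uneven between replicates. The median difference from the controls was 1.52 in the averaged cachexia 3, 5 and 6 and 1.34 in cachexia 4, but 0.28 in cachexia 2 and -0.30 in cachexia 1, and each control lay between -0.35 and 0.30 from the other controls. The class shift was 0.47 without cachexia 4 and 0.49 without the averaged cachexia 3, 5 and 6. On the shared scan day cachexia 1, the 1 cachexia sample there, differed from the controls by -0.30, and on the shared slide by -0.38, and fits with either as a block rest on this sample alone. The replicates with the large class shift were those with the wide GAPDH difference described next.

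**Figure D2:**
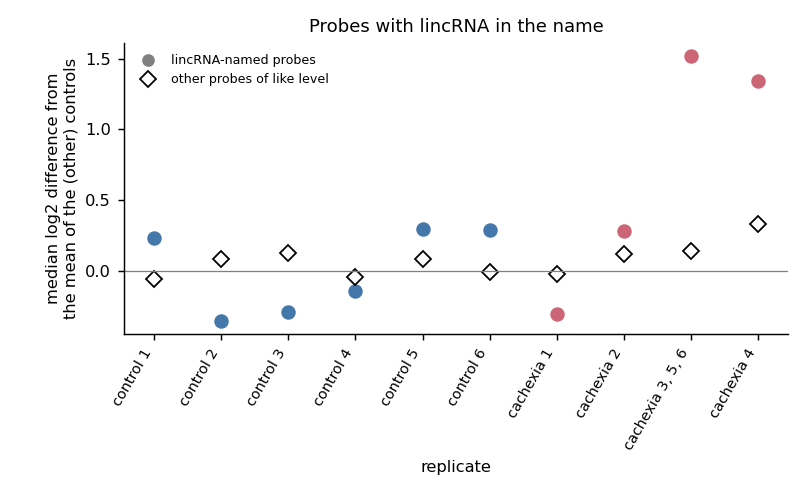
Median log2 difference from the mean of the controls (for a control, of the other controls) over the probes with lincRNA in the name, per replicate (filled circles), and over other probes of like level (open diamonds). Cachexia 4 and the averaged cachexia 3, 5 and 6 lie at 1.34 and 1.52, and all other replicates between -0.35 and 0.30.

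Each array carries mouse control probes for GAPDH, a glycolytic enzyme, and PGK1, another one, under the suffixes 3 and 5, which the files do not define. The signal of GAPDH_3 minus that of GAPDH_5 was 2.79 ± 0.60 (log2, SD, n = 6) in control and 3.82 ± 1.56 (n = 4) in cachexia tissue. It spanned 2.18 to 3.88 on the control arrays, and was 2.52 and 2.47 on cachexia 1 and 2, 4.74 on cachexia 4 and 5.48 to 5.60 on cachexia 3, 5 and 6. The group difference of 1.03 did not pass an exact permutation test (two-sided p = 0.190, adjusted 0.229 over 6 values). GAPDH_3 was 7.76 ± 0.58 in control and 7.16 ± 0.34 in cachexia tissue (difference -0.60, exact permutation p = 0.10), and GAPDH_5 was 4.97 ± 1.08 and 3.34 ± 1.76 (difference -1.63, exact permutation p = 0.110). PGK1_3 was 7.13 ± 0.52 and 6.12 ± 1.35 (difference -1.02, exact permutation p = 0.105). PGK1_5 was well above background in 1 of 10 spots on each of cachexia 3, 5 and 6 and in 10 of 10 on every other array, so on those 3 arrays PGK1_3 minus PGK1_5 has only a lower bound, 6.11 to 6.26, and no group difference is given for it. It spanned 7.73 to 8.56 on the control arrays and was 8.06 and 8.58 on cachexia 1 and 2 and 7.37 on cachexia 4. Without cachexia 3, 5 and 6 it differed between the groups by 0.066 (exact permutation p = 0.893). Adjusted over the 6 values computed, p was 0.193 for each of GAPDH_3, GAPDH_5 and PGK1_3, and the smallest p that the 210 splits allow is 0.00476. Without cachexia 3, 5 and 6 the GAPDH difference was 0.46 (exact permutation p = 0.524), that of GAPDH_5 -0.90 (exact permutation p = 0.298) and that of PGK1_3 -0.42 (exact permutation p = 0.369). The GAPDH difference passed unadjusted without cachexia 2 (1.48, exact permutation p = 0.0476), and PGK1_3 passed without cachexia 1 (-1.36) or cachexia 2 (-1.37), at the same exact permutation p. With 12 separate arrays the GAPDH difference was 1.61 (exact permutation p = 0.0411), and GAPDH_3, GAPDH_5 and PGK1_3 also passed unadjusted.

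**Figure D3:**
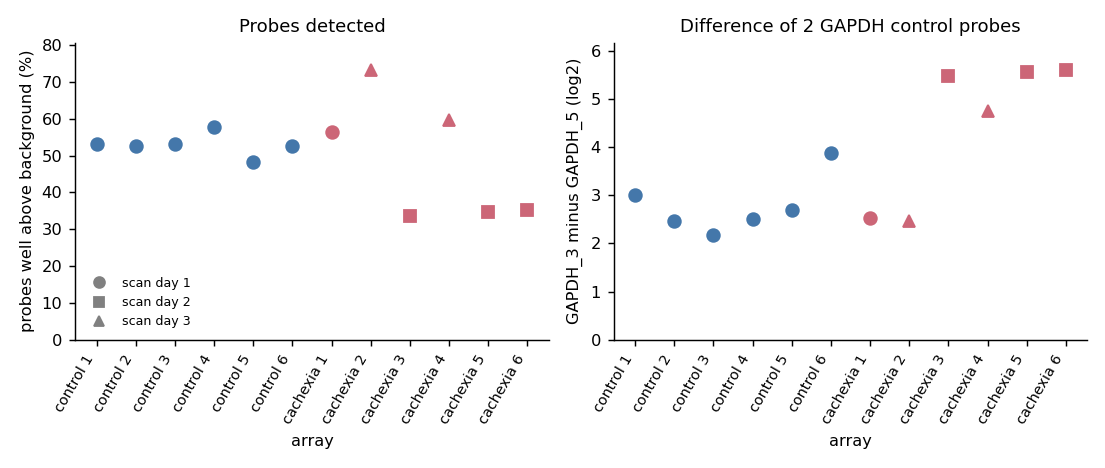
Share of probes well above background (left, %) and the log2 signal of mouse GAPDH_3 minus GAPDH_5 (right), 1 point per array, blue for control, red for cachexia, with the scan day as the marker shape. Cachexia 3, 5 and 6 have the lowest shares, 33.6% to 35.3%, and the widest differences, 5.48 to 5.60.

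The first principal component of the tested probes held 60.2% of the variance and the second 13.5%. On the first, the averaged cachexia 3, 5 and 6 scored 302.1 and cachexia 4 scored 220.1, while cachexia 1 and 2 scored -125.8 and -69.9, within the control range of -157.1 to 49.8. The median SD of a probe was 0.56 between controls and 0.98 between cachexia replicates on the log2 scale, and 76.0% of probes had the larger SD in cachexia tissue.

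**Figure D4:**
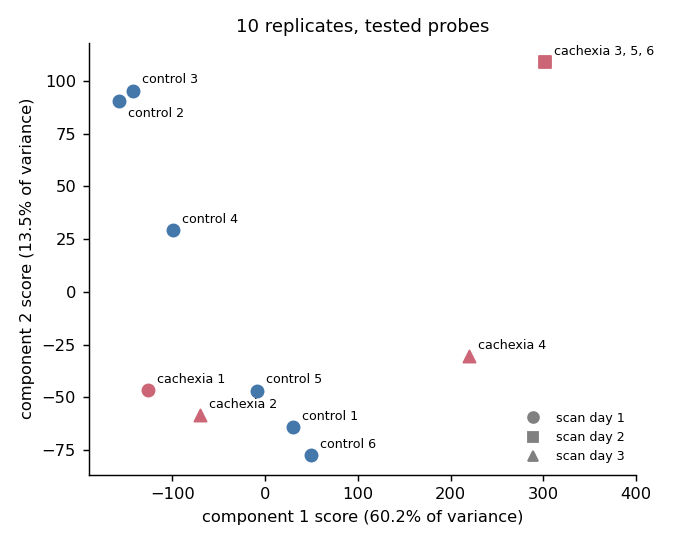
Scores of 6 control (blue) and 4 cachexia (red) replicates on the first 2 principal components of the scaled log2 signals, with the scan day as the marker shape. Cachexia 1 and 2 score -125.8 and -69.9 on the first component, among the controls, and cachexia 4 and the averaged cachexia 3, 5 and 6 score 220.1 and 302.1.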

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

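The comparison with matched lists was set before its result was seen, and the other tests here were chosen after the patterns were seen.

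Control 4 lay apart from the other controls in PGK1_3 minus PGK1_5, at 8.56 against 7.73 to 7.93, and in its 75th percentile signal, at 229.2 against 86.7 to 124.1. Of 20 groups of values examined for such gaps 2 were found, both in this array, and chance gives about 1 in 20. The 300 spots of negative-control name are repeated spots of 15 probes, so they are not 300 separate measurements. Of these spots, 22 were well above background on cachexia 2 and 22 on cachexia 4, against at most 4 on a control array. The control probe E1A a107, not used in any comparison, read 5108 on cachexia 2, 4116 on cachexia 3, 12690 on cachexia 4, 4287 on cachexia 5 and 4864 on cachexia 6, against at most 2408 on a control array. It read 904 on cachexia 1. These readings are not scaled to the array. The 75th percentile signal was 204.3 on cachexia 1, 401.1 on cachexia 2, 94.0 on cachexia 4 and 25.4 to 27.5 on cachexia 3, 5 and 6. On the controls that signal was 86.7 to 229.2. Across the controls, the E1A readings rose in the same order as the scores on the first component. They ran from 197 on control 2 (score -157.1) to 2408 on control 6 (score 49.8). Cachexia 1 and 2 departed from this order. The reading of 5108 on cachexia 2 came with the highest 75th percentile signal, 401.1. On cachexia 3, 5 and 6 the readings were above, and the 75th percentile signals below, those of every control. The relation of the E1A readings to the first component was not tested formally, nor was its cause.

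Cachexia 3, 5 and 6 were nearly identical. If they were 3 animals, probes that vary most between controls should vary more among them than stable probes do. The spread of the most variable 10% of probes over that of the most stable 10% was 1.37 among these arrays, and 1.83 to 5.30 in the 20 triples of controls. One RNA sample on 3 arrays is a candidate explanation, and 3 animals with very similar tissue stay possible, since the test was chosen after the likeness was seen.

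Cachexia 4 and the averaged cachexia 3, 5 and 6 stood apart on the first component. Scan day stays open: cachexia 2 and 4, scanned on 1 day, lay 3.54 times as far apart as cachexia 4 and cachexia 3, 5 and 6 of different days, but this rests on cachexia 2 alone and follows from the pattern itself. Degraded RNA stays open too. Reading it from GAPDH assumes that the undefined suffixes 3 and 5 mean transcript ends. It also assumes that a difference between ends follows degradation after random priming along whole transcripts, which was not tested. Each probe's slope on the GAPDH difference within the 6 controls correlated across probes with its difference from the control mean. The r was 0.51 in the averaged arrays and 0.68 in cachexia 4, and 17 and 13 of 720 orders of the control values gave an r as high. Against that reading, the PGK1 difference of 7.37 on cachexia 4 lay below the control range of 7.73 to 8.56, and the 6.11 to 6.26 on cachexia 3, 5 and 6 is only a lower bound, with PGK1_5 near background, and decides nothing. A difference in wasting between animals stays open and untested. So does the cause of the E1A readings, whose order across the controls was that of this component.

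Probes with lincRNA in the name were dimmer than others (median level -1.79 against -0.34), so scaling of dim probes could raise them. Their median difference of 0.79 lay at percentile 100 of 10000 lists of other probes matched on level, whose median was 0.19 and highest 0.41, which argues against level as the whole cause. Background handling stays open. The shift was 0.23 with normexp on the median signal over the same 330 probes, but the offset of 50 added there shrinks differences of dim probes. Over the 106 probes of the class well above background on all 12 arrays the shift was 0.88. RNA quality and the biology of cachexia stay open too: the replicates that carry the shift are those with the wide GAPDH difference, so the value of 0.18 with that difference as a covariate does not separate them.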

How the results depend on the processing

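Of 34 alternatives, 32 called 0 probes, as did the comparison with cachexia 3, 5 and 6 averaged. The exceptions were the fit planned at first, with 12 separate arrays (10 probes, 10 at least 2-fold), and, chosen after seeing the data, removal of the arrays with a wide GAPDH difference (30 and 30). The former counts 3 nearly identical arrays separately, and for the latter the cause was not tested. The lincRNA-named shift of 0.79 was -0.38 with slide as a block or within slide 2, and -0.30 with scan day as a block or within scan day 1, all of which compare cachexia 1 alone with controls. It was -0.063 without the wide-difference arrays, which carry the shift. It was 0.23 with normexp at an offset of 50, 0.36 over the 1836 probes of the class without a filter, and 0.18 with the GAPDH covariate. Over the 106 probes of the class well above background on all 12 arrays it was 0.88. With an estimated correlation 0.79 no longer passed camera's test. The cause of these changes was not tested. PGK1_3 minus PGK1_5 has only a lower bound in cachexia 3, 5 and 6, so its group difference is given without them only, at 0.066, and its dependence on them cannot be read. The named probes were chosen for groups that do not overlap, which fixes their direction in fits on fewer or averaged arrays (adjusted p over the 4 from 0.00752 to 1.00), and ASMM10P022623 alone passed in 2 of 34 alternatives. The median of all probes moved to -0.12 with quantile normalization and with the authors' values, and to 0.20 without a filter. Replicate numbers did not pair samples (correlations -0.53 to 0.44, own number highest in 0 of 6). With the replicate block 0 probes were called, and 0 with 12 separate arrays and the block. Alternatives for gene lists, mRNA and the per-gene tests were not run. Low signal limits cachexia 3, 5 and 6, where about 35.3% of probes at most were well above background.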

Other observations

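The tests here were chosen after the data were seen.

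Of 32480 probes measured in all 10 replicates, 799 had no overlap between the groups, 383 higher and 416 lower in cachexia tissue. That is 2.46%, and chance gives 0.952% for 6 against 4. Across all 210 splits of the replicates, 19 gave as many such probes, the real one included, and the highest other gave 7798, with control 1, control 6, cachexia 4 and the averaged cachexia 3, 5 and 6 on 1 side, so chance is not excluded.

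For the limma counts, 100 of the 210 splits were drawn. The real split called 0 probes, so all 100 gave as many, and this comparison decides nothing about chance for the count of changed probes, of probes changed at least 2-fold or of lincRNA-named probes. Of the 99 other splits, 96 also called 0 and 3 called any. The highest gave 5953 probes, 5808 of them at least 2-fold and 76 lincRNA-named, with control 1, control 5, cachexia 4 and the averaged cachexia 3, 5 and 6 on 1 side. A split that calls so many points to a structure of the samples other than the groups.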
